A study of Homo sapiens with 12 samples.

How the data were processed

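The data are RNA-seq gene tables of cells labelled as the human prostate cancer lines LNCaP, which is androgen-sensitive, and PC3, which is androgen-independent. Each line was exposed to DMSO, the solvent, or to erastin at 5 µmol/L. Erastin is a small molecule that blocks cystine uptake by system xc- and is used to trigger ferroptosis, an iron-dependent form of cell death. There were 12 libraries in 4 groups of 3, grouped by the labels. Exposure time was not given in the sources used here. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

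Per the labels' protocols, RNA was extracted with TRIzol and libraries were made from total RNA with an Illumina TruSeq RNA kit. HISAT2 version 2.0.5 and genome build hg38 were used, per the submitters' processing notes. The counting tool, its strand setting and its treatment of reads that match several genes were not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain, histone and ribosomal protein genes among them. The authors deposited FPKM values, fragments scaled by gene length and library depth, in 1 table per cell line. Gene lengths were read from the same tables.

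Both tables kept the steps of whole reads. FPKM multiplied by gene length was a whole multiple of 1 step per library for 100% of values above 0, within a tolerance of 0.1 reads. The reads recovered this way numbered 14047979 to 17668554 per LNCaP library and 13709558 to 16350657 per PC3 library. The depth implied by the step was 0.871 to 1.12 times the recovered reads in LNCaP and 0.907 to 1.02 times in PC3, so the deposited FPKM carry a further scaling between libraries whose method was not given in the sources used here.

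The tables use different annotation releases. All 58735 gene identifiers and coordinates of the LNCaP table match GENCODE v29. The PC3 table holds 61221 genes, 58503 of them shared by identifier. Of the shared genes, 5107 have another symbol and 14428 another length. The PC3 table also has 545 unannotated loci. Lines were therefore fitted within their own tables, genes were matched by identifier, and FPKM levels were not tested between lines. Symbols are those of each table, so the same gene can be AARS in LNCaP and AARS1 in PC3.

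Values were analysed as log2(FPKM + 1), and all fold changes are on that scale, which understates changes of low genes. Genes with at least 1 FPKM in at least 3 of the 6 libraries of a line were kept. Erastin was compared with DMSO in each line with limma version 3.58.1 in R version 4.3.3 (moderated test with a variance trend, two-sided, Benjamini-Hochberg adjustment over all genes kept, threshold 0.05). The difference between the lines was the interaction in 1 limma fit of all 12 libraries over genes kept in both. A set of 27 gene lists was tested where at least 5 members were kept, with limma's camera at a preset correlation of 0.01, adjusted over the lists of both lines. Camera compares a list with the other genes. Camera with an estimated correlation, and fry, which asks whether a list's own genes move one way on balance, were alternatives. Overlaps of calls between lines were tested with Fisher's exact test. Plots were drawn with matplotlib version 3.10.9.

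The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named, per line, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those past the test with all 3 erastin libraries on one side of all 3 DMSO libraries. It added up to 4 members of each list past its test, the 6 largest differences between the lines in each direction, and 20 genes whatever their result. Some genes that the rule takes are not reported here. Markers of each line and of stromal cells, leukocytes and endothelium were listed beforehand too.

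Alternatives covered the pseudocount (0.1 and 0.5), the filter (none, or a mean of at least 5 FPKM), quantile, median-ratio and protein-coding scaling, the variance prior, limma voom on the recovered reads, replicate number as a block, both lines in 1 fit, and each library left out. Removal of a gene length trend (lowess, span 0.5), alone and with the block, and leaving out replicate 3 of both LNCaP groups were added after seeing the data.

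Replicate numbers come from the labels' titles. In LNCaP, deviations from the group means of same-numbered DMSO and erastin libraries correlated across genes at 0.254, 0.347 and 0.744 for replicates 1, 2 and 3. Libraries of different numbers reached 0.612, so whether the numbers are pairs is undecided. The blocked count is therefore given beside the LNCaP count. No pair of replicates agreed within sampling noise: the lowest chi-square per degree of freedom was 3.96.

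The fits were tested on simulated reads drawn from the real means and depths with 200 changed genes. Of genes changed 2-fold, 74.0% were recovered among 13551 tested in the LNCaP simulation and 74.2% among 13609 in that of PC3. The share was 100% in each at 4-fold, with 16 and 21 false calls. For the difference between lines, over 11151 genes, 36.1% were recovered at 2-fold and 98.8% at 4-fold, with 10 false calls. The simulated list shift was called in each line and no other list was. Reads were drawn independently for each gene at a dispersion of 0.02, so simulated libraries shared no deviations across genes. The simulation therefore cannot show how often lists are called falsely in the real libraries.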

Results

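The libraries measured RNA of cells labelled as the prostate cancer lines LNCaP and PC3, under DMSO or erastin, with 3 libraries per group. Recovered reads ranged from 13709558 to 17668554 per library. The design asks which genes differ with erastin in each line, and where the lines differ in their response. Values are FPKM means ± SD with n = 3 per group, and positions are on hg38.

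LNCaP libraries under erastin had lower androgen-responsive and cell cycle transcripts and higher transcripts of 11 of 25 targets of NRF2, the transcription factor of the antioxidant response. None of these list calls held with an estimated correlation: by limma camera with Benjamini-Hochberg adjustment, the adjusted p = 0.106 for androgen-responsive genes, 0.129 for DNA replication, 0.129 for G2/M and 0.605 for NRF2 targets with an estimated correlation. Fry, which tests only a list's own genes, called each, with Benjamini-Hochberg adjusted p of 8.87e-07, 0.000158, 0.000168 and 0.00766 in that order. It called 15 of the 25 lists tested in LNCaP. KLK3, which encodes prostate-specific antigen (chromosome 19, 50854915 to 50860764), fell from 207 ± 24.1 to 16.6 ± 2.19 FPKM, a log2 fold change of -3.56 ± 0.16 (SE; limma, Benjamini-Hochberg adjusted p = 0.000138). RRM2, a subunit of ribonucleotide reductase, fell from 20.2 ± 4.41 to 1.53 ± 0.616. HMOX1, which encodes the heme-degrading heme oxygenase 1 (chromosome 22, 35380361 to 35394214), rose from 19.9 ± 2.30 to 109 ± 12.1, a log2 fold change of 2.39 ± 0.15 (limma, Benjamini-Hochberg adjusted p = 0.000241). SLC7A11, the cystine transporter subunit that erastin targets, had 26.4 ± 5.00 and 27.6 ± 2.88 FPKM and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.767).

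Among protein-coding genes past the test with separated groups, the largest rise was that of HIST1H2BC, a histone H2B gene (chromosome 6, 26114873 to 26123926), with a log2 fold change of 3.71. ID1, an inhibitor of DNA-binding transcription factors, rose by 3.48 from 5.51 ± 2.12 to 70.1 ± 16.2 FPKM. HIST2H2BE, HIST1H2BD and HIST1H2AC, further histone genes whose near-identical copies make their values uncertain, rose by 2.65, 2.22 and 2.14, TP53INP2, an autophagy factor, by 2.29, and SERPINI1, a serine protease inhibitor, by 2.28. Reads of mitochondrial ribosomal RNA were 1.67% to 2.46% of a library under DMSO and 2.73% to 3.54% under erastin. The largest falls after KLK3 were those of SYT4, a synaptotagmin, KLK2, a kallikrein, and TMEFF2, with log2 fold changes of -3.54, -3.41 and -3.15. FAM111B, CENPM, a centromere protein, and CDC45, a replication fork factor, followed with -3.13, -3.06 and -3.03.

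Of 36 measured DNA replication genes, 35 fell, among them MCM7, a subunit of the replicative helicase, by 2.99 and CDT1, a licensing factor, by 2.84. The median log2 fold change was -1.80, and 35 fell when adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 3.19e-22). The adjusted p = 0.129 with an estimated correlation. Of 29 G2/M and mitosis genes, 28 fell (29 adjusted over the list alone), with a median of -1.47. CDK1, the mitotic kinase, had a log2 fold change of -2.64, AURKB -2.26, UBE2C -2.06 and TOP2A -1.97. The list's limma camera Benjamini-Hochberg adjusted p was 2.65e-16, and the adjusted p = 0.129 with an estimated correlation.

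Of 24 androgen-responsive genes, 19 fell and 1 rose (20 and 1 adjusted over the list alone). ABCC4, an efflux transporter, had a log2 fold change of -2.00, and TMPRSS2, a serine protease, fell from 172 ± 4.72 to 44.8 ± 0.410. The list's median was -1.18 (limma camera, Benjamini-Hochberg adjusted p = 1.97e-09; adjusted p = 0.106 with an estimated correlation). Of the 10 LNCaP line markers, which overlap this list, 8 fell.

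Of 34 genes of the ATF4 amino acid response, which supply amino acids and one-carbon units, 29 fell (30 adjusted over the list alone, with 1 rise), with a median of -1.19. PCK2 and MTHFD2, mitochondrial enzymes, each had a log2 fold change of -2.21, and PSAT1, of serine synthesis, and TRIB3, a stress-induced pseudokinase, each had -2.14. The list had a limma camera Benjamini-Hochberg adjusted p of 1.07e-11, and the adjusted p = 0.129 with an estimated correlation. Of 20 cytosolic aminoacyl-tRNA synthetases, 16 fell (17 adjusted over the list alone), among them GARS (-1.70), AARS (-1.53), VARS (-1.43) and IARS (-1.42). For this list the limma camera Benjamini-Hochberg adjusted p was 5.91e-07, and the adjusted p = 0.453 with an estimated correlation.

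Of 25 NRF2 targets, 11 rose and 0 fell (13 rose adjusted over the list alone). OSGIN1, AKR1C3 and SRXN1 rose by 2.08, 1.74 and 1.66 on the log2 scale. NQO1, a quinone reductase, rose from 32.1 ± 8.66 to 100.04 ± 20.2 FPKM and TXNRD1, thioredoxin reductase, from 70.7 ± 0.693 to 189.8 ± 2.98. By limma camera, the list's Benjamini-Hochberg adjusted p was 6.96e-05, and the adjusted p = 0.605 with an estimated correlation. Of 24 autophagy and lysosome genes, 11 rose (13 adjusted over the list alone), among them SQSTM1 (1.59), GABARAPL1 (1.43), ULK1 (1.18) and CTSD (0.91). As a list, they had a limma camera Benjamini-Hochberg adjusted p of 0.000134, and the adjusted p = 0.515 with an estimated correlation. The CTSD call ended, with limma Benjamini-Hochberg adjusted p of 0.0693 to 0.115, without any 1 of DMSO 1, DMSO 2 and the 3 erastin libraries, at 0.106 with no filter on low values and at 0.117 with both lines in 1 fit.

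Of 24 p53 targets, 14 fell and 1 rose (15 and 2 adjusted over the list alone). GDF15, a secreted stress factor, DDB2 and SPATA18 had log2 fold changes of -1.62, -1.54 and -1.49, and FDXR -1.39. Camera in limma gave a Benjamini-Hochberg adjusted p of 0.000195, and the adjusted p = 0.129 with an estimated correlation. Of 11 interferon response genes, 5 rose and 1 fell, over all genes and adjusted over the list alone. IFIT2, IRF7 and IFI44 rose by 1.44, 1.41 and 1.12, and OAS3 fell by 1.42. For this list the limma camera Benjamini-Hochberg adjusted p was 0.00875, and the adjusted p = 0.430 with an estimated correlation. Among 74 cytosolic ribosomal protein genes 1 fell, and 0 passed adjusted over the list alone, with a median of -0.44. By limma camera, the list's Benjamini-Hochberg adjusted p was 0.00440, the adjusted p = 0.855 with an estimated correlation, 0.361 with fry, 0.302 without DMSO 3 and 0.0962 without erastin 2.

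In all, 4312 of 13683 genes passed the limma test in LNCaP, 1894 higher and 2418 lower. Of these, 320 and 936 differed by at least 1 on the log2 scale. In 46.5% of the genes tested the groups did not overlap, against 10% by chance. With replicate number as a block the count was 6893. It was 2225 without erastin 1, 2588 without erastin 2 and 2721 without DMSO 2. Scaling to the protein-coding total, which moved the median of all genes to 0.15 in both lines, gave 2519 higher and 1757 lower LNCaP genes, and quantile normalization gave 2680 and 2389. Camera called 10 lists, 3 higher and 7 lower, but other divisions of the 6 libraries gave up to 11, and 0 were called with an estimated correlation (5 at an unadjusted p under 0.05, and 15 by fry).

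**Figure D1:**
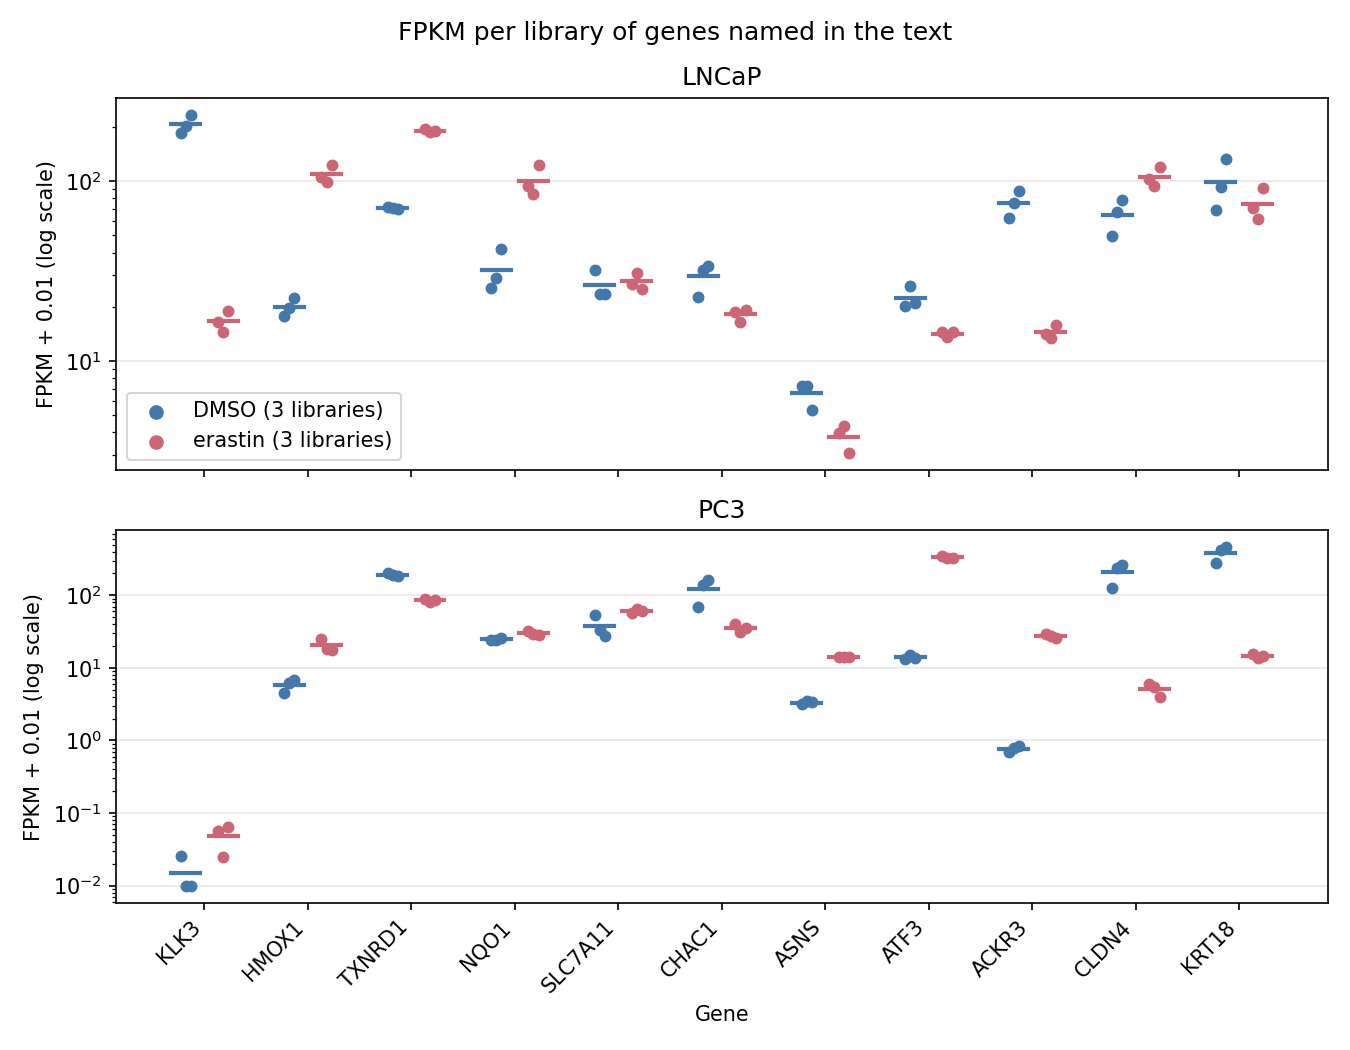
FPKM plus 0.01 of each library on a log axis for 11 named genes in LNCaP (upper panel) and PC3 (lower panel), with DMSO in blue and erastin in red; points are the 3 libraries of a group and bars their means. LNCaP KLK3 lies at a mean of 207 under DMSO and 16.6 under erastin, and PC3 ATF3 at 13.9 and 333.

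The libraries labelled PC3 and erastin had lower epithelial junction, keratin and lipid synthesis transcripts than those labelled PC3 and DMSO. None of these list calls held with an estimated correlation: by limma camera with Benjamini-Hochberg adjustment, the adjusted p = 0.129 for epithelial genes, 0.129 for cholesterol synthesis and 0.453 for fatty acid genes with an estimated correlation. Fry called each, with Benjamini-Hochberg adjusted p of 5.16e-05, 0.000158 and 0.000238 in that order, among 18 of the 26 lists tested in PC3. CLDN4, a tight junction claudin (chromosome 7, 73799542 to 73832693), fell from 208 ± 71.1 to 5.16 ± 1.06 FPKM, a log2 fold change of -5.03 ± 0.29 (SE; limma, Benjamini-Hochberg adjusted p = 2.33e-05). KRT18, a keratin of simple epithelia, fell from 384 ± 94.1 to 14.6 ± 1.06. ATF3, a stress-induced transcription factor (chromosome 1, 212565334 to 212620777), rose from 13.9 ± 1.02 to 333 ± 13.2, a log2 fold change of 4.49 ± 0.11 (limma, Benjamini-Hochberg adjusted p = 4.50e-06). SLC7A11 (chromosome 4, 138164097 to 138242349) rose from 38.0 ± 13.6 to 60.4 ± 3.30 (limma, Benjamini-Hochberg adjusted p = 0.0337), a call that ended, at 0.0739 to 0.102, without any 1 of DMSO 2, DMSO 3 and the 3 erastin libraries, and at 0.0715 with no filter.

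PCDH19, a protocadherin (chromosome X, 100291644 to 100410273), had the largest rise among such genes in PC3, from 0.0169 ± 0.00442 to 39.2 ± 1.14 FPKM. PYGM, muscle glycogen phosphorylase, rose by 5.29 on the log2 scale, SERPINI1 by 5.03, PEG10, a retrotransposon-derived imprinted gene, by 4.75 and RNF225 by 4.61. MYLIP, a ubiquitin ligase, and ARRDC3, an arrestin-domain protein, rose by 4.39 and 4.36. EREG, an EGF receptor ligand (chromosome 4, 74365145 to 74388749), had the largest fall on the log2(FPKM + 1) scale, with a log2 fold change of -5.66. GCNT3, a mucin glycosyltransferase, DKK1, a secreted Wnt inhibitor, and S100A14 had -5.46, -5.08 and -4.96. F3, which encodes tissue factor, CLDN7 and CALB1, a calcium-binding protein, had -4.86, -4.82 and -4.72.

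All 14 measured epithelial genes fell (14 adjusted over the list alone), with a median of -2.81; KRT8 fell from 428 ± 84.1 to 26.9 ± 1.95 FPKM. As a list, they had a limma camera Benjamini-Hochberg adjusted p of 5.91e-07, and the adjusted p = 0.129 with an estimated correlation. Of the 10 PC3 line markers 9 fell, including CAV1, a caveolar coat protein, from 235 ± 38.4 to 32.0 ± 2.01 and FOSL1, an AP-1 subunit, from 304 ± 91.0 to 30.2 ± 2.28. CTNNA1, a gene known as homozygously deleted in PC-3 and looked at only after the data were seen, had 52.8 ± 3.36 FPKM under DMSO and 6.23 ± 0.347 under erastin.

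Of 74 ribosomal protein genes, 56 fell and 1 rose (57 and 1 adjusted over the list alone), with RPL3, RPL34, RPS14 and RPS3 at log2 fold changes of -1.62, -1.62, -1.57 and -1.50. Camera in limma gave a Benjamini-Hochberg adjusted p of 2.36e-08, and the adjusted p = 0.596 with an estimated correlation. Of 20 aminoacyl-tRNA synthetases, 17 fell (18 adjusted over the list alone), with WARS1 at -1.96, AARS1 at -1.75, SARS1 at -1.69 and VARS1 at -1.56. For this list the limma camera Benjamini-Hochberg adjusted p was 9.12e-05, and the adjusted p = 0.129 with an estimated correlation. Of 46 nuclear-encoded oxidative phosphorylation genes, 24 fell and 3 rose, over all genes and adjusted over the list alone. UQCRC1, ATP5F1B and UQCRC2 had -1.39, -1.34 and -1.28, and NDUFV2 rose by 2.06. By limma camera, the list's Benjamini-Hochberg adjusted p was 0.0128, and the adjusted p = 0.677 with an estimated correlation.

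Of 25 cholesterol synthesis genes 16 fell and 1 rose, over all genes and adjusted over the list alone. SREBF2, the transcription factor of the pathway, had a log2 fold change of -2.36 and FDFT1, squalene synthase, of -1.85. As a list, they had a limma camera Benjamini-Hochberg adjusted p of 0.00115, and the adjusted p = 0.129 with an estimated correlation. Of 18 fatty acid genes 12 fell and 2 rose, over all genes and adjusted over the list alone, with SREBF1 at -3.77, FASN, fatty acid synthase, at -2.64, ME1 at -2.32 and ACLY at -2.08. Camera in limma gave a Benjamini-Hochberg adjusted p of 0.0135, the adjusted p = 0.453 with an estimated correlation, and 0.0518 without DMSO 1.

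Of 32 ATF4 response genes, 22 fell and 7 rose (23 and 7 adjusted over the list alone). GDF15, PCK2 and MTHFD2 had log2 fold changes of -3.43, -3.11 and -2.85, whereas ATF3, named above, and ASNS, asparagine synthetase, rose, the latter by 1.79 on the log2 scale. For this list the limma camera Benjamini-Hochberg adjusted p was 0.00455, and the adjusted p = 0.596 with an estimated correlation. Of 25 glutathione and cysteine genes, 15 fell and 3 rose, over all genes and adjusted over the list alone. GPX2, a glutathione peroxidase (chromosome 14, 64939152 to 64942905), fell from 101 ± 12.1 to 3.20 ± 0.815 FPKM; MPST, MGST1 and GSTP1 had -2.37, -2.25 and -1.98. By limma camera, the list's Benjamini-Hochberg adjusted p was 0.00484, and the adjusted p = 0.224 with an estimated correlation. Of 26 NRF2 targets, 16 fell and 4 rose, over all genes and adjusted over the list alone. AKR1B10 had -2.52, TKT, transketolase, -2.40 and TXNRD1 -1.15, and HMOX1 rose by 1.65. As a list, they had a limma camera Benjamini-Hochberg adjusted p of 0.0303, the adjusted p = 0.487 with an estimated correlation, 0.0929 under quantile normalization and 0.0535 without DMSO 3.

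In all, 10214 of 15371 genes passed the limma test in PC3, 5232 higher and 4982 lower, and 2945 and 2648 of them differed by at least 1 on the log2 scale. Among protein-coding genes 3522 were higher and 4298 lower, and scaling to the protein-coding total gave 5821 higher and 4216 lower over all genes. In 71.9% of the genes tested the groups did not overlap, against 10% by chance. The first principal component separated the groups and held 85.8% of the variance, against 63.2% in LNCaP. DMSO 1 stood apart from the other PC3 DMSO libraries: it lay at 48.6 on the second component (9.92% of the variance) against -15.1 and -28.8, and its chi-square per degree of freedom was 71.5 and 107 against them, with 8.58 between them. It was nearer to the erastin libraries for SREBF1, at 25.5 FPKM against 53.4 and 55.4, for CLDN4, at 127 against 239 and 259, and for GDF15, at 154 against 443 and 485. Without it 12354 genes passed, 6185 higher and 6169 lower. Genes with a value above 0 numbered 25679 to 26144 per library under DMSO and 30239 to 31311 under erastin, and mitochondrial ribosomal RNA took 0.628% to 0.944% and 1.95% to 2.18% of reads. Camera called 9 lists, all lower, but other divisions of the 6 libraries gave up to 9, 0 were called with an estimated correlation (4 at an unadjusted p under 0.05, and 18 by fry), and quantile normalization gave 1 higher and 8 lower.

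**Figure D2:**
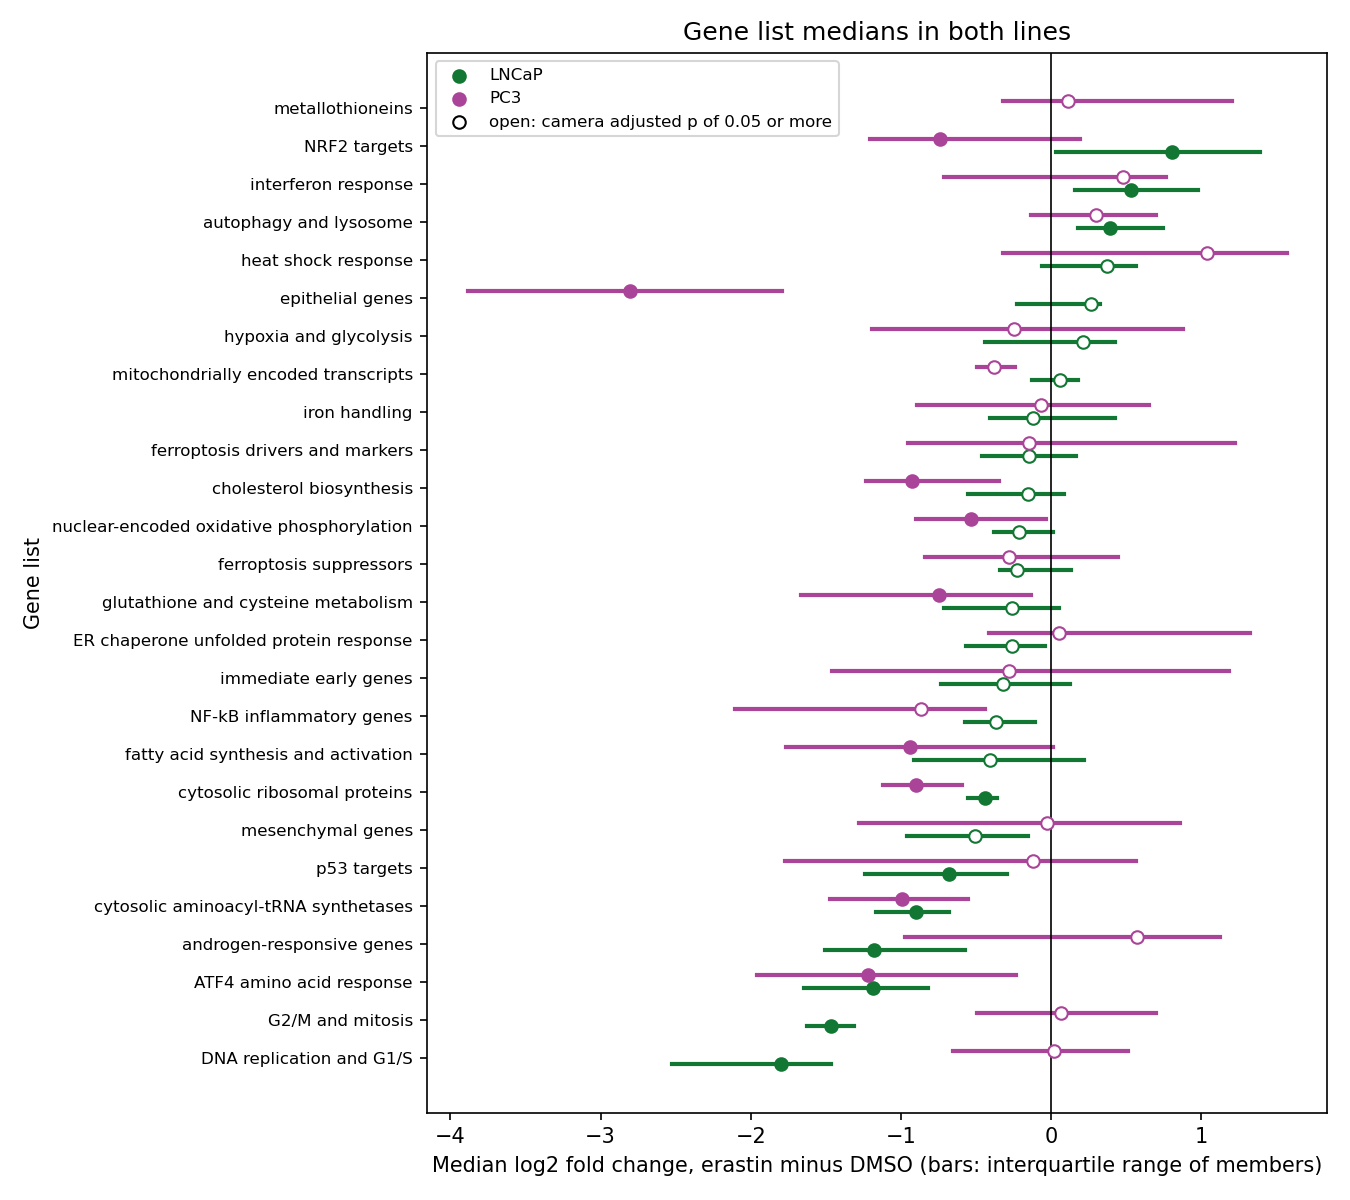
Median log2 fold change, erastin minus DMSO, of each gene list in LNCaP (green) and PC3 (purple); bars span the interquartile range of members, and open points have a camera adjusted p of 0.05 or more. DNA replication genes lie at -1.80 in LNCaP and 0.022 in PC3, and epithelial genes at 0.26 and -2.81.

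The lines differed in their response for DNA replication, epithelial and androgen-responsive genes, the lists whose call held with an estimated correlation (limma camera, Benjamini-Hochberg; adjusted p = 0.0377, 0.00872 and 0.0377 with an estimated correlation). ACKR3, an atypical chemokine receptor (chromosome 2, 236567787 to 236582354), fell from 75.5 ± 12.9 to 14.4 ± 1.16 FPKM in LNCaP and rose from 0.762 ± 0.0661 to 27.5 ± 1.39 in PC3, a difference of log2 fold changes of -6.31 ± 0.19 (SE; LNCaP minus PC3, limma interaction, Benjamini-Hochberg adjusted p = 5.45e-09). GPX2 rose from 0.451 ± 0.166 to 2.56 ± 0.212 in LNCaP and fell in PC3, a difference of 5.91 ± 0.22 (limma interaction, Benjamini-Hochberg adjusted p = 8.53e-09). TXNRD1 rose by 1.41 in LNCaP, had -1.15 in PC3, and differed by 2.56 (limma interaction, Benjamini-Hochberg adjusted p = 8.21e-07).

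SYT4, PEG10, ATF3, VGF, a secreted neuropeptide precursor, and FAM111B had the next lowest differences, from -5.71 to -4.78; each rose in PC3. CLDN4, SPINT1, a protease inhibitor, CLDN7, EPHA1, an ephrin receptor, and KRT18 had the next highest, from 5.74 to 4.23; each fell in PC3. These values hold for the PC3 group labels as given. With those labels exchanged, a calculation made after the data were seen, the differences would be 1.72 for ACKR3, 4.35 for PEG10, 3.87 for ATF3 and 2.16 for VGF, and -3.31 for GPX2, -4.33 for CLDN4, -2.60 for SPINT1, -5.26 for CLDN7, -4.11 for EPHA1 and -4.95 for KRT18. SYT4 and FAM111B would have -1.37 and -1.48, and TXNRD1 0.26. In LNCaP, PEG10, CLDN7, EPHA1 and KRT18 did not pass the test. With replicate number as a block PEG10 (-0.40) and CLDN7 (-0.44) did, at limma Benjamini-Hochberg adjusted p of 0.0452 and 0.0329, and PEG10 missed it in 13 of 20 alternatives. ATF3 lost its LNCaP call without erastin 1 or 2 (limma, Benjamini-Hochberg adjusted p of 0.0595 to 0.0608) and under protein-coding scaling (0.105). CLDN4 lost its call there without any 1 of DMSO 1, DMSO 2 and the erastin libraries (limma, Benjamini-Hochberg adjusted p of 0.0714 to 0.123), with no filter (0.0881) and with both lines in 1 fit (0.0624).

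Of 36 DNA replication genes tested in both lines, 33 had a lower response in LNCaP (34 differed adjusted over the list alone), and the medians were -1.80 in LNCaP and 0.022 in PC3 (limma camera, Benjamini-Hochberg adjusted p = 1.22e-15; adjusted p = 0.0377 with an estimated correlation). Of 13 epithelial genes 12 had a higher response in LNCaP, over all genes and adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 1.42e-09; adjusted p = 0.00872 with an estimated correlation). Of 15 androgen-responsive genes 10 were lower and 1 higher (12 differed adjusted over the list alone; limma camera, Benjamini-Hochberg adjusted p = 0.000770; adjusted p = 0.0377 with an estimated correlation). The calls of another 4 lists ended with an estimated correlation: G2/M genes (26 of 28 lower; adjusted p = 0.169 with an estimated correlation), NRF2 targets (15 of 23 higher and 1 lower; adjusted p = 0.379 with an estimated correlation), cholesterol synthesis (9 of 24 higher; adjusted p = 0.368 with an estimated correlation) and ER chaperones (9 of 22 lower and 1 higher; adjusted p = 0.624 with an estimated correlation). Adjusted over the list alone, 27, 17, 11 and 10 members of these differed. All of these list calls hold for the PC3 labels as given, and an exchange would turn the sign of the PC3 medians. For epithelial genes the medians were 0.26 in LNCaP and -3.25 in PC3, so that difference would turn negative. Androgen-responsive genes (-0.95 in LNCaP and 0.57 in PC3) and NRF2 targets (0.80 and -0.57) would then have medians of the same sign in both lines.

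In all, 5248 of 11823 genes differed in response by the limma interaction. For 330 the gene rose in LNCaP and fell in PC3, and for 353 the reverse. Both lines had 823 rises in common against 503 for independent lists (odds ratio 2.62, 95% interval 2.35 to 2.91, Fisher's exact test, p = 1.46e-70) and 1040 falls against 672 (odds ratio 2.51, interval 2.28 to 2.77, p = 7.63e-77). The fold changes had a Spearman correlation of 0.307 across genes, which are not independent replicates. Fisher's test treats genes as independent too, so its intervals and p-values do not measure the spread between samples. Among calls of at least 1 on the log2 scale, 380 were shared in direction, against 1863 among all calls. These overlaps too hold for the PC3 labels as given: with them exchanged, 683 calls would be shared in direction, the correlation would be -0.307, and 7118 genes and, by camera at the preset correlation, 13 lists would differ in response, in place of 5248 and 7.

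**Figure D3:**
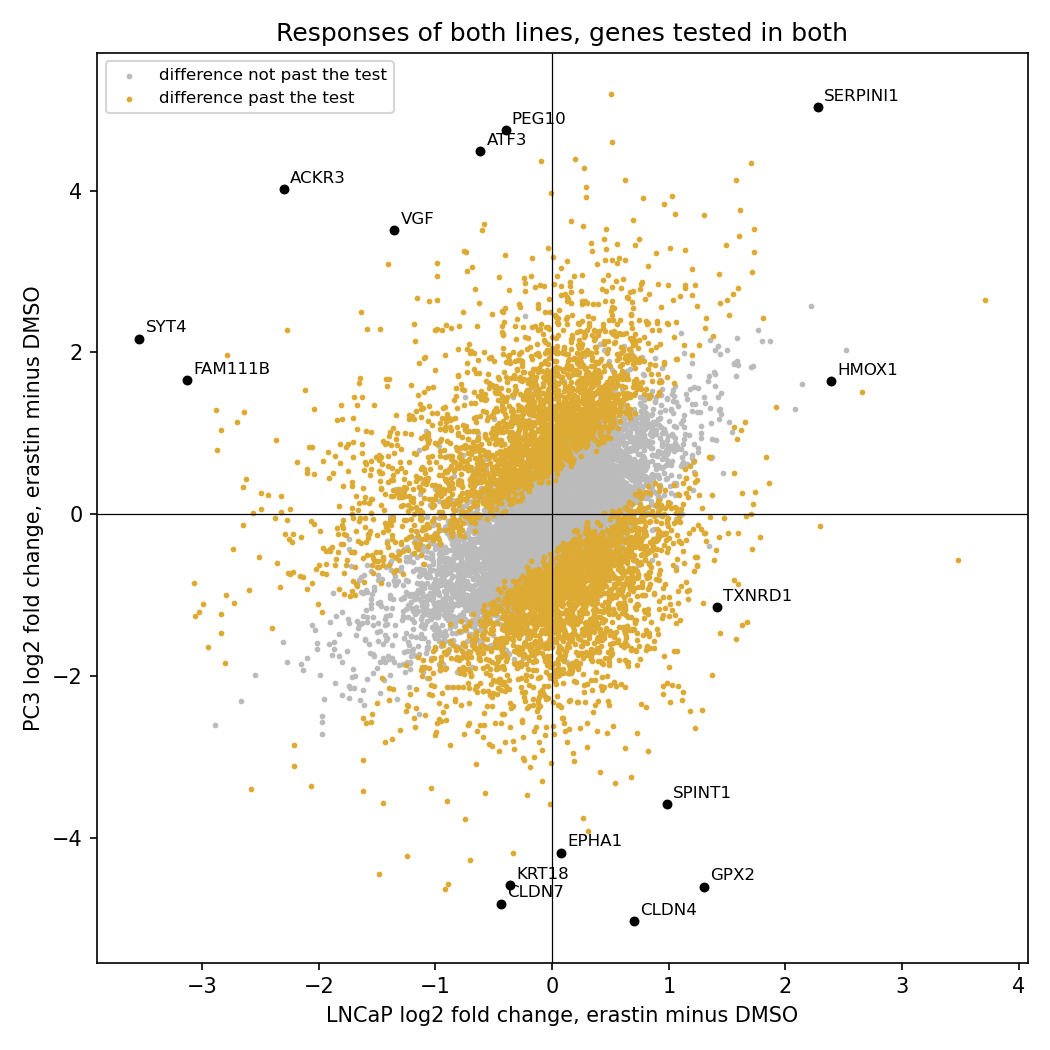
Log2 fold change, erastin minus DMSO, of the 11823 genes tested in both lines, LNCaP on the horizontal and PC3 on the vertical axis; yellow points passed the test of the difference and black points are labelled genes. ACKR3 lies at -2.30 and 4.01, and GPX2 at 1.30 and -4.61.

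Genes tied to erastin and ferroptosis were given whatever their result. CHAC1, a glutathione-degrading enzyme, fell from 29.4 ± 5.82 to 18.1 ± 1.46 FPKM in LNCaP and from 123 ± 47.6 to 35.9 ± 4.58 in PC3. In LNCaP, ATF4 fell by 1.14 on the log2 scale, DDIT3 by 0.77, ASNS by 0.67 and CDKN1A, a cell cycle inhibitor, by 0.62; ACSL4, an activator of polyunsaturated fatty acids, rose by 0.58 and GCLM by 0.80. All of these LNCaP calls but that of GCLM ended without 1 of several libraries: the highest limma Benjamini-Hochberg adjusted p was 0.101 for CHAC1, 0.0749 for ATF4, 0.149 for DDIT3, 0.0777 for ASNS, 0.0662 for CDKN1A and 0.0694 for ACSL4, and leaving out DMSO 2 or erastin 1 ended each of them. Leaving out erastin 2 did so for all but ASNS, DMSO 1 for DDIT3 and ASNS, DMSO 3 for DDIT3 and CHAC1, and erastin 3 for ASNS and CHAC1. With no filter on low values the limma Benjamini-Hochberg adjusted p was 0.0607 for CHAC1, 0.0562 for ATF4, 0.112 for DDIT3 and 0.0571 for ASNS. Calls also ended for DDIT3 at a pseudocount of 0.1 (0.0509) and with a robust variance prior (0.0534), for ASNS under protein-coding scaling (0.193) and for CHAC1 with both lines in 1 fit (0.0815). In PC3, DDIT3 rose by 1.55, CDKN1A by 1.74, TFRC, the transferrin receptor, by 1.17 and VDAC2, a mitochondrial channel, by 1.22. ACSL4 had -0.98, TRIB3 -0.77 and GPX4, the lipid peroxide reductase, -0.74; the TRIB3 and GPX4 calls ended without any 1 of DMSO 2, erastin 2 and erastin 3, with highest limma Benjamini-Hochberg adjusted p of 0.0684 and 0.0731. TRIB3 also lost its call under quantile normalization (-0.38; limma, Benjamini-Hochberg adjusted p = 0.0558) and GPX4 with no filter (0.0508).

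Several did not pass the test. In LNCaP these were SLC3A2 (-0.26), GPX4 (-0.22), TFRC (-0.33), FTH1, a ferritin subunit (0.87), VDAC2 (-0.25) and VDAC3 (-0.11). With replicate number as a block FTH1 and TFRC did pass (limma, Benjamini-Hochberg adjusted p = 0.0178 and 0.0384), and FTH1 missed the test in only 10 of 21 alternatives, with a lowest adjusted p of 0.000334 under quantile normalization. In PC3 they were SLC3A2 (0.04), ATF4 (-0.32), NQO1 (0.26), GCLM (-0.39), FTH1 (0.11) and VDAC3 (-0.18); without DMSO 1, FTH1 had -0.40 and ATF4 -0.49 (limma, Benjamini-Hochberg adjusted p = 0.0350 and 0.00463). NQO1 passed without DMSO 1, with the gene length trend removed and under each of 3 other scalings (limma, Benjamini-Hochberg adjusted p of 0.0112 to 0.0313). KLK3 was below the filter in PC3, at means of 0.00515 FPKM under DMSO and 0.0385 under erastin. The lists of ferroptosis suppressors and of ferroptosis drivers did not pass camera in either line (limma, Benjamini-Hochberg adjusted p of 0.514 and 0.578 in LNCaP, 0.674 and 0.995 in PC3), nor did iron handling (0.995 and 0.625). Their members moved both ways: in PC3, 5 of 18 suppressors rose and 7 fell, 7 and 8 of 21 drivers, and 6 and 9 of 23 iron genes. In LNCaP these were 1 and 4 of 16, 3 and 5 of 19, and 4 and 3 of 23. Fry passed for drivers in LNCaP and PC3 (Benjamini-Hochberg adjusted p = 0.0325 and 0.00168) and for iron handling in PC3 (0.00679). It did not for iron handling in LNCaP (0.960) or suppressors (0.167 and 0.0677). The camera direction and the median differ in sign for iron handling in LNCaP and for DNA replication and ferroptosis drivers in PC3. Another 4 comparisons, of PC3 lists that did not pass camera, have a median and mean of unlike sign: DNA replication, ferroptosis drivers, interferon response and mesenchymal genes.

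Among markers of other cells, COL1A1, a fibroblast collagen, rose in LNCaP from 1.10 ± 0.0942 to 2.65 ± 0.294 FPKM, and CD14, a monocyte receptor, rose in PC3 from 0.227 ± 0.173 to 1.33 ± 0.160, where PECAM1, an endothelial adhesion molecule, fell from 1.06 ± 0.0321 to 0.445 ± 0.0475. KDR, an endothelial receptor, also passed the test in PC3, where it fell from 28.9 ± 2.63 to 4.17 ± 0.260 FPKM, and COL1A1 did not pass there. The rest of these markers, in either line, were below the filter and were not tested. The highest other group means were 3.59 for stromal, 1.49 for leukocyte and 1.06 for endothelial markers. Of the PC3 line markers, the highest in LNCaP was TM4SF1 at 8.53 ± 2.48 under DMSO, and of the LNCaP line markers, the highest in PC3 was TMPRSS2 at 5.63 ± 0.771 under DMSO.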

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

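The tests below of cell line identity, gene length and library scaling for the PC3 response, of library scaling and exchanged labels for the ATF4 genes and of shared handling were chosen only after the result was seen; the counts of other divisions of the libraries were planned.

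The responses of the lines differed for 5248 genes by the limma interaction. Of 100 pairs of divisions of the 6 libraries of each line, 1, the real one, gave as many, and the highest other gave 4478. The divisions exchange treatment labels within a line, so they ask whether either line responds, not whether the responses are equal. They therefore cannot decide whether the difference arose by chance. The highest other pair kept the real PC3 groups, whereas pairs that kept neither real grouping gave at most 1. The count therefore rests mostly on the PC3 groups. In each line alone, 10 divisions are too few for a share under 0.05: the real ones gave 4312 genes in LNCaP and 10214 in PC3, and the highest other gave 0 in both (1 of 10 as large in each; limma, at an unadjusted p under 0.05, 1816 and 602 against 5900 and 10724).

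Among lists the real count was not set apart. For the difference between lines, 55 of 100 pairs gave as many as the 7 lists called, and the highest other gave 11, so chance is not excluded. Within a line 10 divisions are too few for a share under 0.05: LNCaP gave 10 lists with 11 as the highest other (4 divisions gave at least as many), and PC3 gave 9 with 9 (3 divisions). Of the LNCaP divisions that part all 3 pairs of replicate numbers, as the real one does, the highest other gave 10 lists and 0 genes. The lists that differed by median, LNCaP minus PC3, were DNA replication at -1.85, G2/M at -1.54, epithelial genes at 3.57, NRF2 targets at 0.96, androgen-responsive genes at -1.04, cholesterol synthesis at 0.59 and ER chaperones at -0.47. These hold for the PC3 labels as given. With them exchanged, the PC3 medians of epithelial genes (-3.25, against 0.26 in LNCaP) and NRF2 targets (-0.57, against 0.80) would change sign. The epithelial difference would then turn negative. By limma camera with Benjamini-Hochberg adjustment, 4 of these calls ended: the adjusted p = 0.169 for G2/M, 0.379 for NRF2 targets, 0.368 for cholesterol synthesis and 0.624 for ER chaperones with an estimated correlation.

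Single genes whose response differed between the lines by the limma interaction, with log2 differences LNCaP minus PC3, were GPX2 at 5.91, CLDN4 at 5.74, SPINT1 at 4.57, CLDN7 at 4.37, EPHA1 at 4.27 and KRT18 at 4.23. On the other side were ACKR3 at -6.31, SYT4 at -5.71, PEG10 at -5.15, ATF3 at -5.11, VGF at -4.86 and FAM111B at -4.78. Among the genes named whatever their result, TXNRD1 differed by 2.56, ACSL4 by 1.56, NQO1 by 1.36, GCLM by 1.19, CHAC1 by 1.01 and HMOX1 by 0.74, and ASNS was at -2.46, CDKN1A at -2.36, DDIT3 at -2.32, TFRC at -1.50, VDAC2 at -1.48 and TRIB3 at -1.36. With the PC3 labels exchanged, the first 6 would have 0.26, -0.41, 1.89, 0.41, -2.32 and 4.04, in the order given. ASNS, CDKN1A, DDIT3, TFRC, VDAC2 and TRIB3 would have 1.13, 1.12, 0.78, 0.84, 0.97 and -2.91. The calls for CHAC1 and HMOX1 ended without any 1 of 10 and of 8 libraries, with limma Benjamini-Hochberg adjusted p up to 0.107 and 0.0821. Both also ended at a pseudocount of 0.1 (limma, Benjamini-Hochberg adjusted p = 0.0514 and 0.0684) and with the replicate block (0.0682 and 0.0564), CHAC1 with no filter (0.0700) and HMOX1 with voom (0.0696).

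The size of the PC3 response, 10214 genes, was weighed first. Removing a gene length trend left 10279 genes and the lowest of 3 other scalings 10037, which argues against either as the whole cause. Whether the erastin libraries came from another cell line, or from a mixture, cannot be told apart from a wide response: 291 protein-coding genes differed at least 10-fold between the PC3 groups, 39.2% of the 742 between the DMSO libraries of the lines, against 21 in LNCaP. The 742 sets FPKM levels of tables with different annotation releases side by side. Of their shared genes 14428 have another length, so counts between the lines are a rough yardstick, here and in the first version below. A first version of this test counted genes above 5 FPKM in all libraries of one group and under 0.1 in all of the other, and gave 11 against 224 (4.91%), under the 10% bound set for excluding another line; it was set aside after that value was seen, since a small share of mixed RNA would lift such genes over 0.1. The 10 LNCaP line markers had a median of 0.228 FPKM in the PC3 erastin libraries, with STEAP2 highest at 3.02, against a median of 38.5 in LNCaP under erastin. These values argue against LNCaP as the source of those libraries, or as a large part of a mixture. A line other than LNCaP, a mixture with such a line and a biological response to erastin stay open.

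CTNNA1 reads in PC3 were weighed with it. The lowest of the 6 libraries, under erastin, had 5.92 FPKM of CTNNA1, as a line without the deletion known for PC-3 would show. The PC3 DMSO libraries had 52.8 ± 3.36, and LNCaP had 36.8 ± 1.22 under DMSO and 57.4 ± 1.67 under erastin, from another annotation release. By this gene the question of another line covers the libraries labelled PC3 and DMSO too. Values per gene do not show which exons the reads cover, so reads of a partly deleted gene stay open, and a biological explanation was not tested.

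Lower ATF4 response genes, against the rise often described for erastin, were the third pattern. The highest list median over 3 other scalings was -1.02 in LNCaP and -1.02 in PC3, which argues against scaling. Exchanged labels of the groups would put NRF2 targets higher in DMSO: their median was 0.80 in LNCaP, opposite to that, and -0.74 in PC3, as an exchange there would give. In LNCaP the lists point to different sides, so an exchange is neither needed nor excluded. In PC3 an exchange could account for both lists but so could a real fall, and HMOX1 (1.65), ATF3 (4.49), ASNS (1.79), DDIT3 (1.55) and SLC7A11 (0.71, a call that single libraries end) were higher under erastin there.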

How the results depend on the processing

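Removal of the gene length trend, alone or with the block, and leaving out pair 3 were chosen after seeing the data; the other alternatives were planned. Counts that differed from the reported one by 1.5 times or more were as follows. A mean of at least 5 FPKM gave 2572 genes in LNCaP, 5240 in PC3 and 2476 for the difference, from fewer genes tested, and no filter gave 15 lists in LNCaP and 9719 genes and 11 lists for the difference. With replicate number as a block LNCaP had 6893 genes, and 7338 with the length trend also removed; the cause was not tested. Limma camera with an estimated correlation left 0 lists in LNCaP, 0 in PC3 and 3 for the difference (5 and 4 in the lines at an unadjusted p under 0.05), and fry gave 15 in LNCaP, 18 in PC3 and 15 for the difference. Calls of at least 1 on the log2 scale shared 380.

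With 1 library left out, LNCaP genes ranged from 2225 to 4209 (2225 without erastin 1, 2588 without erastin 2, 2721 without DMSO 2), PC3 genes from 8659 to 12354 and the difference from 4501 to 6553. Lists ranged from 10 to 11, 8 to 9 and 7 to 9.

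In PC3, same-numbered libraries had deviation correlations of -0.380, -0.0135 and -0.311, against up to 0.377 between different numbers. No pairing by number shows in these values, but centring 3 libraries ties them to each other, so pairing is undecided. The block gave 9068 genes in PC3 and 5469 for the difference. It changed no other count of calls beyond 1.5 times. Limma voom on recovered reads gave 4444, 10296 and 5303 genes in LNCaP, PC3 and the difference.

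More LNCaP genes were lower than higher as reported, but not under quantile normalization (2680 higher, 2389 lower), protein-coding scaling (2519 and 1757) or the block with the length trend removed (3698 and 3640). PC3 calls, mostly higher as reported, were mostly lower at a mean of at least 5 FPKM (2446 higher, 2794 lower) and with both lines in 1 fit (3559 and 3961). Differences, mostly lower as reported (2528 and 2720), were mostly higher at that mean (1259 and 1217), under quantile normalization (3055 and 2693) and protein-coding scaling (2539 and 2490), with the length trend removed (2892 and 2863) and without PC3 DMSO 1 (3290 and 3263). Among the named genes, directions turned only for ones that did not pass the test. Under quantile normalization LNCaP SLC3A2 had 0.032, GPX4 0.14 and VDAC3 0.082, and PC3 ATF4 0.11; protein-coding scaling gave LNCaP VDAC3 0.093, and leaving out pair 3 gave LNCaP EPHA1 -0.039. With 1 library left out, LNCaP SLC7A11 ranged from -0.0056 to 0.22, GPX4 from -0.50 to 0.050, VDAC3 from -0.26 to 0.068 and EPHA1 from -0.033 to 0.17, PC3 SLC3A2 from -0.26 to 0.21 and FTH1 from -0.40 to 0.37, and the difference of VDAC3 from -0.081 to 0.25 and of SLC3A2 from -0.47 to 0.0020. The cause was not tested.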

Other observations

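The histone group, the protocadherins, the unannotated loci, the shared deviation of replicate 3 and their tests were chosen only after the values were seen, except that the bounds for gene length were written before those tests were run.

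Histone genes of the histone clusters were higher under erastin in both lines. In LNCaP 22 of 36 rose and 0 fell, with a median log2 fold change of 1.21, and in PC3 45 of 49 rose and 0 fell, with a median of 1.80. A gene could pass the filter through the erastin libraries alone, as H2AC21 did in PC3, at 0 FPKM under DMSO and 2.06 under erastin. Such genes could hardly be counted as falls, so the counts, medians and tests of this group and of the protocadherins lean upward. How far they lean was not tested. HIST2H2BE went from 19.7 ± 0.893 to 129 ± 2.59 FPKM in LNCaP, and H1-4, a linker histone, had a log2 fold change of 4.34 in PC3. The limma camera Benjamini-Hochberg adjusted p over 4 tests was 3.14e-12 in each line, and the adjusted p = 0.0124 with an estimated correlation in each; with the replicate block the latter was 0.0684 in each. Protocadherins, the other family tested, rose for 7 of 14 genes in LNCaP, and in PC3 9 of 17 rose and 3 fell (adjusted p = 0.200 with an estimated correlation in both). Histone copies are nearly identical, so reads shared among them stay uncertain. In the same libraries mitochondrial ribosomal RNA took 1.67% to 2.46% of reads under DMSO and 2.73% to 3.54% under erastin in LNCaP, and 0.628% to 0.944% and 1.95% to 2.18% in PC3. Genes with a value above 0 numbered 25679 to 26144 and 30239 to 31311 in PC3.

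Removing a gene length trend left histone medians of 1.33 in LNCaP and 1.37 in PC3, which argues against length as the whole cause. Fewer replicating cells in PC3 cannot be told apart: the replication list had a median of 0.022 with 11 members higher and 14 lower. Its bound was reworded after this value was seen, because members that move both ways decide nothing. In LNCaP the replication list fell, with a median of -1.80 and 35 of 36 members lower. Fewer replicating cells therefore stay open there as well, but no test of this was set for LNCaP. Most transcripts of the histone group lack a poly(A) tail, and a change in their polyadenylation, or in how RNA was selected for the libraries, stays open.

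Of 286 unannotated loci tested in the PC3 table, 151 rose and 87 fell. Their share of reads was 0.593% to 0.826% under DMSO and 0.214% to 0.264% under erastin.

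Fold changes of genes 30 places apart along a chromosome correlated at 0.0340 between the PC3 groups, 0.00602 between the LNCaP groups and 0.0417 between the DMSO libraries of the lines, across genes. Their Spearman correlations of mean FPKM were 0.908, 0.970 and 0.856. The values between the lines set FPKM from different annotation releases side by side.

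LNCaP DMSO 3 and erastin 3 deviated together. With the gene length trend removed their correlation was 0.698, which argues against length as the cause. Handling of same-numbered libraries together stays open: the lowest same-number correlation was 0.254, and the highest between different numbers was 0.612. The first bound would have excluded shared handling on those values; it was relaxed after they were seen, because centring 3 libraries ties the correlations to each other.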
